A study of Mus musculus with 8 samples.

How the data were processed

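RNA sequencing of liver was analysed in 8 libraries from 6-month-old mice, 4 WT and 4 Atp7b knockout (KO). Per the labels' protocols, total RNA was extracted with Trizol, treated with DNase and cleaned on Qiagen columns. The submitters' processing notes name FastQC, cutadapt and STAR and the mouse genome build mm10, without versions. The counting program, the strand setting and the annotation release are not given in the sources used here. The table deposited by the authors holds raw counts per gene, whole numbers with a different total in each library, and no normalization was applied before deposit as far as the values show.

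The table lists 54232 genes by versioned Ensembl identifier and symbol. Of these, 54079 (99.7%) had their identifier in the GENCODE M21 annotation of mm10, and 52480 had the same version of it. Coordinates, gene types, GC content and exon lengths were taken from that annotation. Because the strand setting is not given, reads of overlapping or antisense genes cannot be separated here, and reads of near-identical gene copies (Mup, Cyp2c, Cyp3a, Cyp2b, Sult2a, Ugt1a and Klrb1 families) may be split between copies, so values of single members are uncertain.

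Genotypes were taken from the labels. Replicate numbers follow accession order and pair nothing, so no paired fit was made. The numbers in the library names were grouped here into 3 series, called A, B and C. The labels do not call these series batches, and they were used for values within each series and as a covariate in an alternative fit.

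Genes with enough counts were kept with edgeR's filterByExpr, which left 15811 genes. Libraries were scaled with TMM factors, and genotypes were compared with edgeR's quasi-likelihood test (edgeR 4.0.16 with limma 3.58.1 in R 4.3.3) with genotype as the only term. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are log2 values, KO minus WT. Levels are library-size-scaled counts (CPM) on TMM-scaled totals, given as mean ± SD over 4 libraries, and the standard error (SE) of a log2 fold change is its size divided by the square root of the test's F value. Principal components and correlations used log2 CPM with a prior count of 2.

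Where a gene had no count in any WT library, the fold is a lower bound taken against a floor of 3 counts over the WT group. With 1 to 3 counts, the ratio of summed counts is given with its 95% counting interval. These intervals and floors cover counting error only. Per library, 3 counts correspond to 0.129 to 0.425 CPM.

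The genes to be named, the gene lists, the main test and most alternatives were fixed before the data were examined. Named genes are Atp7b, 15 genes of bile acid and metal handling whatever their result, up to 4 members with the lowest p-value in each list, and the 12 largest changes per direction among called genes with a mean of at least 1 CPM and no overlap between genotypes. Names that are only clone or predicted-gene numbers were passed over in that last part, and clone names were read as no symbol.

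There were 26 lists for the study's subject and for cell types, and 8 lists that check for other tissues, sex, time of day and mitochondrial RNA. Each was tested against the other genes with camera at a preset correlation of 0.01 between genes, again with the correlation estimated from the data, and with fry, which asks whether the members move one way and compares them with no other gene. List p-values were adjusted by Benjamini-Hochberg within the 26 and within the 8 lists. For each list, members were also counted after adjustment over the list alone.

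The procedure was tested on simulated data built on the counts of these libraries, with 15539 genes in the simulated fit. It recovered 2 of 67 genes changed 1.5-fold (2.99%), 17 of 67 changed 2-fold (25.4%) and 64 of 66 changed 4-fold (97.0%), with 6 false calls among 89. A list of moved genes was called, and 0 lists of unmoved genes were. Simulated genes varied independently, while the estimated correlation in the real data reached 0.71 for fatty acid and triglyceride synthesis. The simulation therefore cannot show how often camera calls unmoved lists of correlated genes.

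Alternatives covered DESeq2 1.42.0, limma-voom with and without quality weights, robust dispersions, size factors (RLE), upper-quartile factors, library totals only, totals without the 10 most abundant genes, no filter, a stricter filter, an adjusted p under 0.01, the number series as a covariate, removal of chromosome 8, and leaving out each library in turn. An offset for GC content and exon length, the same offset without WT replicate 3, and a clock index as a covariate were added after the data were seen. This clock index was the mean log2 CPM of Dbp, Tef, Nr1d1, Nr1d2 and Per3 minus that of Arntl, Npas2 and Cry1. A sex covariate was not run because all 8 libraries read as male. All 35 splits of the libraries into 4 and 4 were also fitted.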

Results

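Read counts of liver genes were compared between 4 WT and 4 Atp7b KO libraries from mice 6 months old. Atp7b encodes the copper-transporting ATPase that is defective in Wilson disease, and the series title names bile acid physiology in that disease as its subject. Total counts in WT replicates 1 to 4 were 11960162, 17127260, 9880253 and 27530506. In KO replicates 1 to 4 they were 14583961, 17883132, 16244837 and 18423836. Between 19726 and 23119 genes had a count in the WT libraries and between 26082 and 27149 in the KO libraries. The labels do not state that each library is a separate animal, so p-values measure only the spread between these libraries.

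Atp7b RNA was lower in KO than in WT, and some reads of the gene remained in every KO library. In WT replicates 1 to 4 Atp7b (ENSMUSG00000006567.11, mm10 chromosome 8, 21992785 to 22060305, minus strand) read 28.9, 32.0, 9.63 and 27.4 CPM. In KO replicates 1 to 4 it read 8.76, 8.91, 6.50 and 7.15 CPM. The means were 24.5 ± 10.1 (SD, n = 4) and 7.83 ± 1.19 CPM (SD, n = 4). The log2 fold change was -1.65 ± 0.32 (SE), or 3.15-fold lower in KO, with adjusted p = 0.00312 by edgeR's quasi-likelihood test. WT replicate 3 lay close to KO, with an exact Poisson interval of 7.48 to 12.2 CPM against 7.36 to 10.4 for KO replicate 1, and without it the log2 fold change was -1.92. Counts per gene do not show which exons the remaining reads came from.

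The metallothionein genes separated the genotypes without overlap, WT replicate 3 included. Mt1 rose from 4.39 ± 1.54 to 793 ± 309 CPM (182-fold, adjusted p = 2.22e-06). Mt2 rose from 1.67 ± 0.616 to 673 ± 337 CPM (397-fold, adjusted p = 2.62e-06). In WT replicate 3 alone, Mt1 read 6.23 CPM, against a lowest KO value of 427 CPM.

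**Figure D1:**
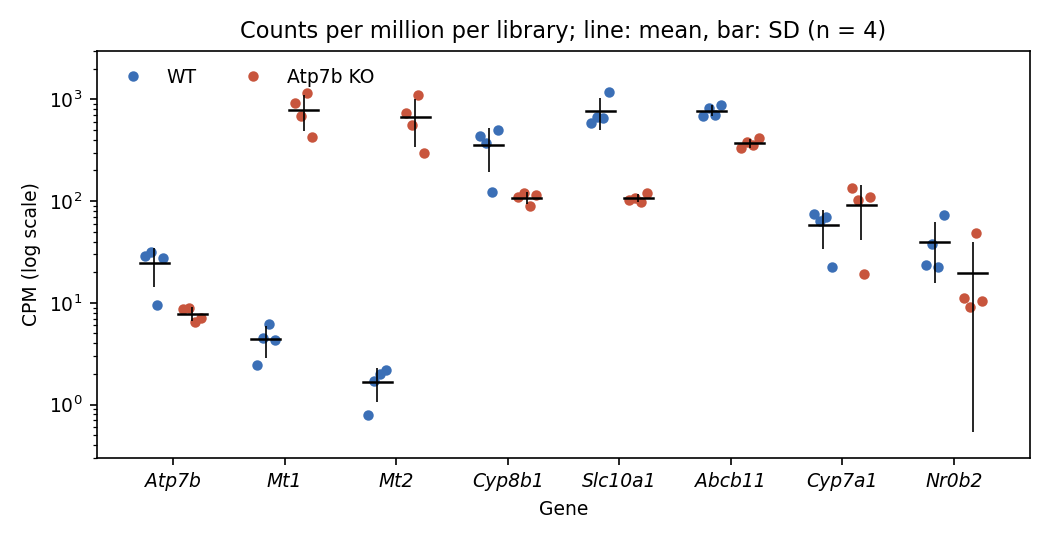
CPM on a log axis for Atp7b, Mt1, Mt2, Cyp8b1, Slc10a1, Abcb11, Cyp7a1 and Nr0b2, with 1 dot per library, a line at the mean and a bar for the SD (n = 4). All 4 KO libraries lie below all 4 WT libraries for Slc10a1 and Abcb11, while the genotypes overlap for Cyp7a1 and Nr0b2.

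The first principal component held 68.3% of the variance and separated the WT from the KO libraries. WT libraries lay from -77.1 to -70.5 and KO libraries from 62.9 to 80.8. The second component held 19.0% and set WT replicate 3, at -92.9, apart from the other WT libraries at 18.0 to 40.7. Correlations of log2 CPM were 0.9751 to 0.9863 between WT libraries other than replicate 3, 0.925 to 0.944 for WT pairs with replicate 3, 0.978 to 0.985 between KO libraries and 0.856 to 0.909 across genotypes. The lowest chi-square per gene between 2 libraries was 23.2, so none repeats another within counting noise.

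**Figure D2:**
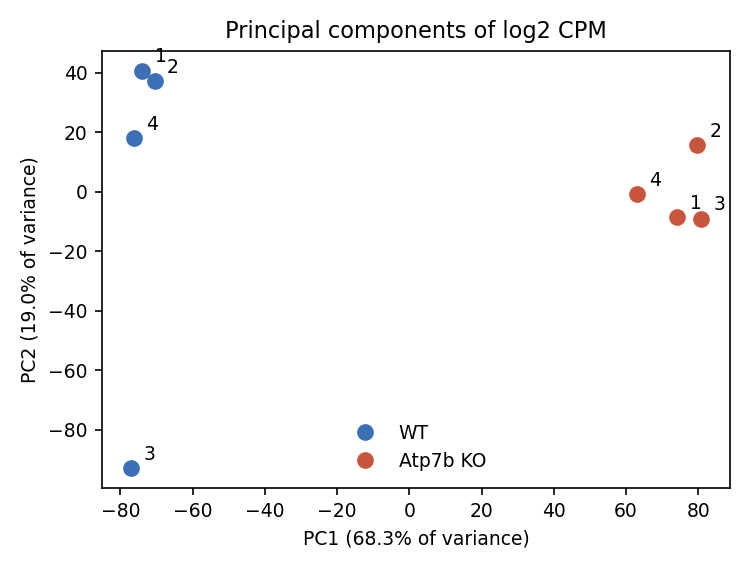
First and second principal components of log2 CPM, with 1 point per library (4 WT, 4 Atp7b KO). The genotypes separate on the first axis, and WT replicate 3 lies at -92.9 on the second.

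Genotype and number series are not the same split. Series A holds 1 WT and 2 KO libraries, series B 1 and 1, and series C 2 and 1. By number, the WT library of series A lies nearer to the series B libraries than to the KO libraries of series A. Differences within series A, and the fit with the series as a covariate, may therefore cross groups of libraries. The Atp7b log2 difference within series A, B and C was -1.70, -0.56 and -2.03, and the Slc10a1 difference was -2.46, -2.75 and -2.87. Cyp8b1 gave -1.93, -0.48 and -1.90. Cyp7a1 did not hold a single direction, at 0.65, -1.85 and 1.55. The series B values compare WT replicate 3 with KO replicate 3 alone. WT replicate 3 was the lowest WT library for Atp7b and Cyp8b1. KO replicate 3 was the lowest KO library for Cyp7a1, at 19.4 CPM against 104 to 136. The series B values may therefore reflect these single libraries rather than the series. With the series as a covariate, the calls of Kdr (adjusted p = 0.0985), Flt1 (0.0955) and Tef (0.0514) were lost, and those of Egfl7 (0.0494), Hbb-bs (0.0118), Hbb-bt (0.0455) and, by camera, the male-biased liver list (0.0208) were gained.

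Across the liver transcriptome, bile duct and cell division genes were among those higher in KO, and Cyp2c and Mup genes were among those lower. Tex19.1, Wfdc12 and Scml2 had no WT count and were read in all 4 KO libraries. Cyp2c29, Cyp2c37 and Cyp2c54 fell.

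Of 15811 genes tested, 4746 (30.0%) were called, 2775 higher and 1971 lower in KO. With library totals only, the split was 4804 higher and 642 lower, and 4485 and 743 with totals that leave out the 10 most abundant genes. At least 2-fold changes were called for 2220 higher and 955 lower genes. Protein-coding genes made up 2388 of the higher and 1623 of the lower calls. The genotypes did not overlap in 4203 of the 4746 called genes, which selection by p-value favours, so this count is no separate evidence for the calls. WT replicate 3 held the number of calls down. Without it 4267 genes were higher and 3837 lower, including 4729 of the 4746. The median log2 fold change of all genes tested was -0.05 with TMM, 0.07 with upper-quartile factors, 0.37 with library totals only and 0.32 with totals that leave out the 10 most abundant genes, so a small fold change is defined only relative to such a shift.

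Among genes without a WT count, Tex19.1 reached 113 ± 26.3 CPM in KO, at least 2204-fold higher, and Wfdc12 45.8 ± 10.2 CPM, at least 899-fold higher. Scml2 was at least 897-fold, Catsperg2 at least 804-fold, Cyp2c65 at least 548-fold and Klrb1 at least 545-fold higher. Muc13, at 21.4 ± 2.48 CPM, was at least 417-fold higher and Mep1a, at 18.8 ± 4.67 CPM, at least 366-fold higher. Sult2a2 and the pseudogene Psg-ps1 were at least 251-fold and at least 226-fold higher. Spink1 had 1 WT count, in replicate 3, and 94.1 ± 14.2 CPM in KO, a ratio of 5401 with a counting interval of 969 to 213350 (adjusted p = 4.38e-07, log2 fold change 11.89, and 13.75 without WT replicate 3). H19, with 5 WT counts, rose to 232 ± 171 CPM (log2 fold change 11.24 ± 0.92, and 12.30 without WT replicate 3). There were 172 genes called higher with at most 3 WT counts and at least 1 CPM in KO, and 2 genes the other way round.

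Of the genes that fell, Cyp2c29 went from 1825 ± 582 to 90.0 ± 29.4 CPM (20.3-fold lower, adjusted p = 7.89e-06). Dct fell from 9.90 to 0.498 CPM (log2 fold change -4.31 ± 0.44), Cyp2c37 by 4.25, Cyp2c54 by 3.62 and Ugt1a5 by 3.49 on the log2 scale. Ctcflos, an antisense gene whose reads cannot be told from its partner's, fell by 4.12 and without KO replicate 4 by 5.10. Mup11 fell by 3.71, and without KO replicate 4 by 4.56. WT replicate 3 held the highest WT level of Cyp2c37, Cyp2c54 and Mup11, which were at -3.71, -3.22 and -3.14 without it. It also held the highest level of 5 further genes and widened their fold changes. Slco1a1 was at -4.13 with it and -3.10 without it, Serpina7 at -3.98 and -3.25, Inmt at -3.89 and -2.94, Mup3 at -3.85 and -2.95, and Sult2a8 at -3.64 and -2.86. All 12 stayed called when any 1 library was left out.

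Bile acid genes, the subject in the title, were more often called lower than higher in KO. The main uptake transporter Slc10a1, the 12-alpha-hydroxylase Cyp8b1, the sterol 27-hydroxylase Cyp27a1, the conjugating enzymes Baat and Slc27a5 and the canalicular pump Abcb11 fell. Of the basolateral export genes, Abcc4 and Slc51b rose, Abcc3 fell and Slc51a was not called. Cyp7a1, the first enzyme of the classic pathway, was not called in either direction.

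Slc10a1 fell from 767 ± 271 to 107 ± 10.1 CPM (log2 fold change -2.84 ± 0.25, 7.15-fold lower, adjusted p = 2.21e-05). Cyp8b1 fell from 358 ± 165 to 108 ± 13.8 CPM (-1.73 ± 0.36, 3.31-fold lower, adjusted p = 0.00453). In WT replicate 3, Cyp8b1 read 124 CPM, close to the highest KO value of 119 CPM, and without that library its log2 fold change was -2.02. Cyp27a1 fell from 472 ± 115 to 188 ± 29.1 CPM (-1.33 ± 0.22, adjusted p = 0.00132). Baat went from 413 ± 110 to 186 ± 26.7 CPM (-1.15 ± 0.22, adjusted p = 0.00246) and Slc27a5 from 901 ± 113 to 465 ± 75.7 CPM (-0.96 ± 0.19, adjusted p = 0.0036). Abcb11 went from 775 ± 95.8 to 371 ± 37.0 CPM (-1.06 ± 0.17, adjusted p = 0.00108) and Abcc3 from 249 ± 99.4 to 51.4 ± 6.07 CPM (-2.28 ± 0.31, adjusted p = 3.1e-04). Abcc4 rose from 1.46 ± 0.396 to 6.27 ± 1.33 CPM (2.09 ± 0.27, adjusted p = 2.27e-04). Slc51b rose from 0.174 ± 0.115 to 4.25 ± 1.06 CPM (4.37 ± 0.40, and 5.12 without WT replicate 4).

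Cyp7a1 read 57.7 ± 23.96 CPM in WT and 92.4 ± 50.6 CPM in KO (0.68 ± 0.52, adjusted p = 0.364), a difference within the spread between replicates. Cyp7b1 (-0.69 ± 0.30, adjusted p = 0.109) was not called, but was with the GC and length offset (adjusted p = 0.0245, and 0.0137 without WT replicate 3). Cyp2c70 (0.45 ± 0.17, adjusted p = 0.0676) was higher in all 4 KO libraries and was called without WT replicate 3 (adjusted p = 0.0317), with DESeq2 (0.0108), quality weights (0.00688), upper-quartile factors (0.0268), library totals only (0.00451) and totals without the 10 most abundant genes (0.0049). Nr0b2, the short heterodimer partner, was not called (-0.99 ± 0.58, adjusted p = 0.228). Without KO replicate 3, Nr0b2 was at -1.95 with adjusted p = 0.0089, and with all 8 libraries it was called with quality weights (-1.44, adjusted p = 0.0134) and without a filter (-0.99, adjusted p = 0.0425). The bile acid receptor Nr1h4 was called lower (-0.55 ± 0.17, adjusted p = 0.0362). That call was lost without WT replicate 1 (adjusted p = 0.0659) and without KO replicate 1, 2, 3 or 4 (0.0529, 0.108, 0.109 and 0.0617), and with library totals only (0.600), without the 10 most abundant genes in the totals (0.438), with upper-quartile factors (0.0855), with no filter (0.0986) and with the clock covariate (0.062).

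**Figure D3:**
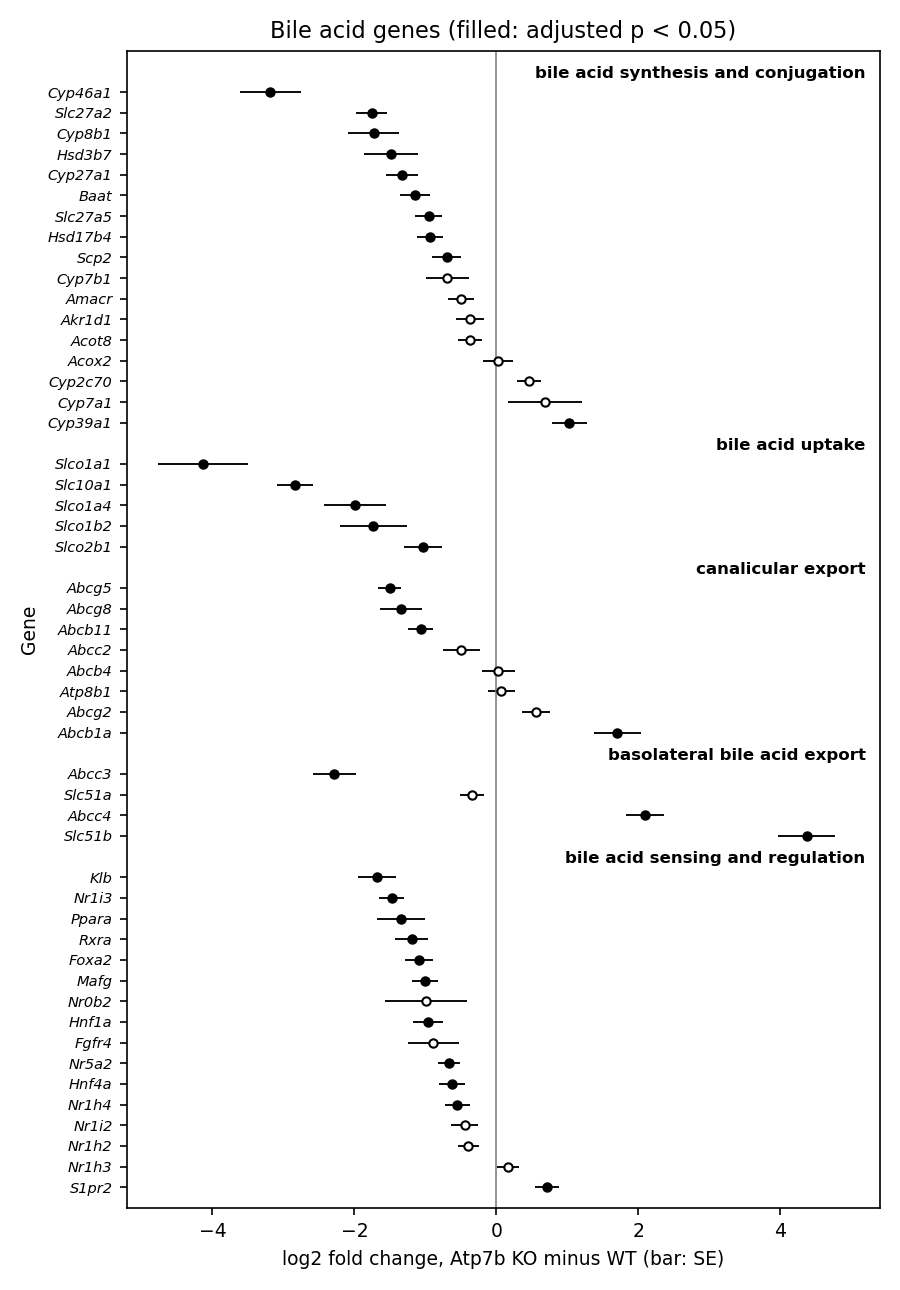
Log2 fold changes (Atp7b KO minus WT) with SE bars for the 50 bile acid genes tested, by list, filled where the adjusted p is under 0.05. Of these, 28 are called lower and 5 higher, and Slc51b and Slco1a1 lie farthest from 0.

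Over the 5 bile acid lists, 28 of 50 genes tested were lower and 5 higher, or 18 and 9 with library totals only. Hepatocyte markers had a median log2 fold change of -0.74, close to the -0.70 of bile acid synthesis, while cholangiocyte (3.67), stellate cell (1.39) and macrophage (0.94) medians lay above 0, and levels per cell type were not measured here. Of 17 synthesis and conjugation genes, 9 were lower and 1 (Cyp39a1, 1.03) higher, or 10 and 2 adjusted over the list alone, with a median log2 fold change of -0.70. Slc27a2 (-1.76) and Cyp46a1 (-3.19) were among those lower. The list ranked below other genes (camera adjusted p = 0.00124), with adjusted p = 0.0809 with an estimated correlation. All 5 uptake genes were lower in both counts, with a median of -1.99 (camera adjusted p = 5.7e-04, and adjusted p = 0.0809 with an estimated correlation). Slco1a4 (-1.99), Slco1b2 (-1.73) and Slco2b1 (-1.04) followed Slco1a1 and Slc10a1, and the Slco2b1 call was lost without KO replicate 3 (adjusted p = 0.0504), with library totals only (0.124) and without the 10 most abundant genes in the totals (0.0968). Of 16 sensing and regulation genes, 10 were lower, among them Nr1i3 (-1.47), Klb (-1.68), Foxa2 (-1.09) and Mafg (98.5 to 49.3 CPM), and S1pr2 (0.71) was higher, or 13 and 1 adjusted over the list alone. The Mafg call was lost with library totals only (adjusted p = 0.0632). The median of the list was -0.92 (camera adjusted p = 4.2e-04, and adjusted p = 0.0809 with an estimated correlation).

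Canalicular export split, with Abcb11, Abcg5 (-1.50) and Abcg8 (-1.35) lower and Abcb1a (1.71) higher among 8 genes, or 3 and 2 adjusted over the list alone. Its median was -0.23, and 0.17 with library totals only (camera adjusted p = 0.184, and 0.0488 with DESeq2). Basolateral export had 2 genes higher and 1 lower of 4 by both adjustments, at a median of 0.88 (camera adjusted p = 0.379), and Slc51a (-0.34, adjusted p = 0.155) was not called, but was called lower with the GC and length offset (-0.42, adjusted p = 0.0472). Directional fry tests gave adjusted p = 1.9e-04 for synthesis, 0.00167 for uptake, 0.0297 for canalicular export, 0.00167 for basolateral export and 2.9e-04 for sensing.

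Metal handling beyond Mt1 and Mt2 changed in single genes. The copper importer Slc31a1 (-1.18) and Sco2 (-1.37) fell, and the transferrin receptor Tfrc (1.93) rose. Of 17 copper and metal genes, 3 were higher and 3 lower by both adjustments. The median of that list was -0.16 while the mean was 0.75, which Mt1 and Mt2 raise, and camera pointed up (adjusted p = 0.734). With library totals only the median was 0.28. Of 13 iron genes, 3 were higher and 4 lower by both adjustments, with Slc39a14 (-1.01), Slc11a2 (-0.80) and Trf (-0.81) among the lower. The iron median was 0.07 with a mean of 0.03, and camera pointed down (adjusted p = 0.515). With library totals only the iron median was 0.49, and the calls of Slc39a14, Slc11a2 and Trf were lost (adjusted p = 0.0636, 0.174 and 0.173).

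Lipid genes that passed the test were mostly lower in KO, where hepatocyte markers also had a median log2 fold change below 0 (-0.74) and cholangiocyte markers had a median above 0 (3.67). Scd1 fell from 18629 to 3988 CPM and Elovl5 from 1092 to 182 CPM, while Lpl rose from 15.0 to 111 CPM. Of 20 fatty acid and triglyceride synthesis genes, 15 were lower (17 adjusted over the list alone), with Elovl5 at -2.58, Elovl3 at -2.68, Scd1 at -2.22 and Me1 at -1.39. The median was -1.45 (camera adjusted p = 1.4e-07, and adjusted p = 0.297 with an estimated correlation). Of 20 fatty acid oxidation genes, 15 were lower and 1 higher (17 and 1 adjusted over the list alone), with Acaa1b at -2.51 and Fgf21 at -2.56. The median was -1.01 (camera adjusted p = 1.1e-05, and adjusted p = 0.297 with an estimated correlation). In cholesterol synthesis, 6 of 24 genes were lower by both adjustments, among them Fdps (-2.50), Stard4 (-1.73), Sc5d (-1.58) and Tm7sf2 (-1.21). The median was -0.62 (camera adjusted p = 0.00201, and adjusted p = 0.45 with an estimated correlation). Among 21 lipoprotein genes, 6 were lower and Lpl (2.90) higher, or 8 and 1 adjusted over the list alone. Pltp (-1.83), Apoa2 (-1.34) and Apoa5 (-1.27) were lower, and the median was -0.65 (camera adjusted p = 0.0204, adjusted p = 0.266 with an estimated correlation, and 0.0597 with the clock covariate).

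Cell division and p53 target genes rose in KO. Cdc20 went from 0.386 to 22.0 CPM, Top2a from 1.40 to 31.5 CPM and Phlda3 from 0.979 to 34.6 CPM. Of 24 cell cycle genes, 21 were higher (22 adjusted over the list alone), with Cdc20 at 5.86, Ccnb1 at 5.44, Ube2c at 5.18 and Top2a at 4.46. The median was 2.48 (camera adjusted p = 5.9e-27, and adjusted p = 0.0229 with an estimated correlation). Of 16 p53 pathway genes, 12 were higher, or 14 higher and 1 lower adjusted over the list alone, with Phlda3 at 5.24, Tnfrsf10b at 4.36, Eda2r at 3.94 and Plk2 at 2.34. The median was 1.46 (camera adjusted p = 2e-08, and adjusted p = 0.0229 with an estimated correlation). These were the 2 of 18 lists called with the preset correlation that were also called with an estimated one. Medians of cholangiocyte (3.67), neutrophil (2.20), stellate cell (1.39), lymphocyte (1.16) and macrophage (0.94) markers also lay above 0. Those of hepatocyte (-0.74) and endothelial markers (-0.55) lay below 0, and levels per cell type were not measured.

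Oxidative stress genes Gsta1 (5.05), Slc7a11 (4.84), Cbr3 (2.78) and Nqo1 (1.70) rose. In that list, 10 of 19 genes were higher and 1 lower (11 and 1 adjusted over the list alone), at a median of 0.73 (camera adjusted p = 5.4e-05, and adjusted p = 0.0809 with an estimated correlation). Endoplasmic reticulum stress genes split, with Asns (3.81, and 4.74 without WT replicate 1) and Atf3 (2.24) higher and Chac1 (-2.17) and Herpud1 (-1.69) lower among 16, the same 2 and 2 by count when adjusted over the list alone. That median was -0.09 against a mean of 0.07, the median was 0.32 with library totals only, and camera pointed down (adjusted p = 0.741).

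Of 22 xenobiotic P450 genes, 9 were lower and 5 higher (10 and 5 adjusted over the list alone), at a median of -0.49, or -0.07 with library totals only (camera adjusted p = 0.0162, adjusted p = 0.297 with an estimated correlation, and 0.0539 with the clock covariate). Cyp3a41a had 1 WT count, in replicate 1, and a ratio of 886 with a counting interval of 159 to 35029 (log2 fold change 9.26, and 11.07 without WT replicate 1). Cyp2b13 had 1 WT count, in replicate 2, and a ratio of 241 with an interval of 42.9 to 9543 (log2 fold change 7.35, and 9.09 without WT replicate 2). Nuclear genes of the respiratory chain had 2 of 22 lower, Atp5a1 (-0.71) and Sdhb (-0.56), or 1 adjusted over the list alone. The Sdhb call was lost without KO replicate 1, 2 or 4 (adjusted p = 0.0608, 0.0636 and 0.0532), with upper-quartile factors (0.0532), no filter (0.0889) and the clock covariate (0.0579). With library totals only and without the 10 most abundant genes, Atp5a1 (0.24 and 0.155) and Sdhb (0.569 and 0.38) both lost their calls. Cox5a (-0.49, adjusted p = 0.076) and Uqcrc1 (-0.51, adjusted p = 0.0656) were not called by edgeR, while DESeq2 called both (0.0455 and 0.0299), as did quality weights and the GC and length offset, and Uqcrc1 was called without WT replicate 3 (0.00286). DESeq2 called 6 and quality weights 7 of the 22. The list median was -0.40, and 0.05 with library totals only. Its camera call (adjusted p = 0.029, and adjusted p = 0.445 with an estimated correlation) was lost without WT replicate 3 (0.0977), without KO replicate 2 (0.0525), with quality weights (0.0769), with library totals only (0.0744), without the 10 most abundant genes in the totals (0.0601) and with the clock covariate (0.141).

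Inflammatory genes rose in part, where macrophage and lymphocyte markers also had medians above 0 (0.94 and 1.16). Among 11 chemokine and signalling genes, 8 were higher (9 adjusted over the list alone), including Ccl5 (1.95), Tlr2 (1.92), Icam1 (1.77) and Vcam1 (1.56), at a median of 0.96 (camera adjusted p = 0.00194, and adjusted p = 0.297 with an estimated correlation). Of 20 acute phase genes, 6 were higher and 2 lower (6 and 3 adjusted over the list alone), with Lcn2 at 3.35, Orm2 at 2.84, Il1rn at 2.78 and Orm3 at 1.81. The median was -0.11 while the mean was 0.47 and camera pointed up (adjusted p = 0.546), and the median was 0.30 with library totals only.

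**Figure D4:**
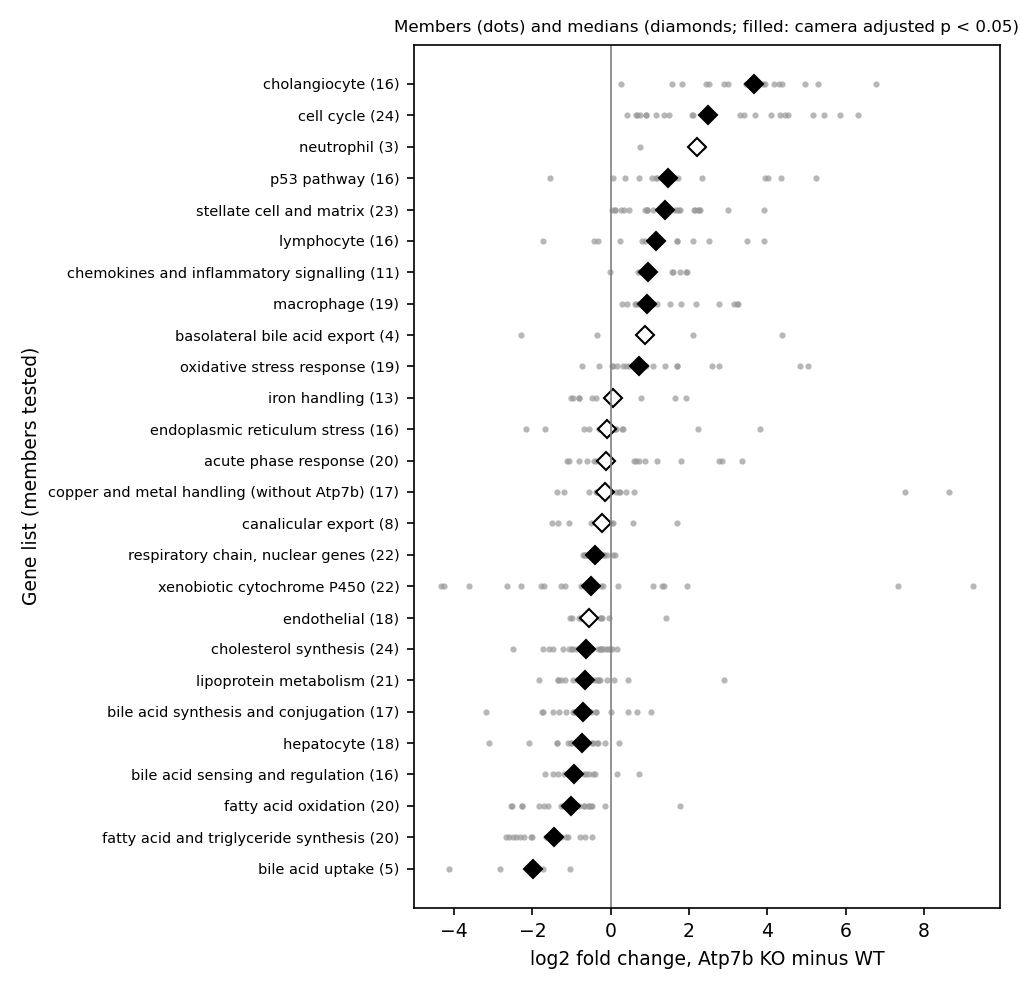
Log2 fold changes (Atp7b KO minus WT) of the members of the 26 study and cell type lists (dots) and their medians (diamonds, filled where camera's adjusted p with the preset correlation is under 0.05). Cholangiocyte genes have the highest median, 3.67, and bile acid uptake the lowest, -1.99.

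Bile duct markers had the highest median among cell type lists, 7 of 18 hepatocyte markers fell, and the median of endothelial markers lay below 0. Spp1 went from 42.9 to 772 CPM, Epcam from 0.713 to 23.7 CPM and Tspan8 from 1.82 to 64.9 CPM. Of 16 cholangiocyte genes, 15 were higher by both adjustments, with Tspan8 at 5.29, Epcam at 4.96, Prom1 at 4.37 and Spp1 at 4.17, at a median of 3.67 (camera adjusted p = 2.4e-12, and adjusted p = 0.201 with an estimated correlation). Of 23 stellate cell and matrix genes, 14 were higher (16 adjusted over the list alone), with Lox at 3.92 (4.61 without WT replicate 1), Timp1 at 2.99, Col3a1 at 2.15 and Thbs2 at 1.78. Their median was 1.39 (camera adjusted p = 1.4e-04, and adjusted p = 0.347 with an estimated correlation). Of 19 macrophage genes, 10 were higher (13 adjusted over the list alone), with Trem2 at 3.26, Cx3cr1 at 2.77, Ccr2 at 2.18 and Mpeg1 at 1.17, at a median of 0.94 (camera adjusted p = 2.6e-04, and adjusted p = 0.297 with an estimated correlation).

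Of 16 lymphocyte genes, 9 were higher and 1 lower (11 and 1 adjusted over the list alone), with Cd8a at 3.91 (3.27 without KO replicate 2), Cd8b1 at 3.49, Gzmb at 2.51 and Cd3g at 2.11. The median was 1.16 (camera adjusted p = 0.0204, and adjusted p = 0.349 with an estimated correlation). That camera call was lost with library totals only (0.0658), without the 10 most abundant genes in the totals (0.0589) and with the stricter filter (0.244). It was also lost with the GC and length offset without WT replicate 3 (0.0706). The neutrophil list had 3 genes tested, with S100a8 (2.35) and S100a9 (2.20, and 2.90 without WT replicate 3) higher by both adjustments and a median of 2.20, and Csf3r (0.76, adjusted p = 0.141) was not called. Camera gave adjusted p = 0.139 for it, 0.036 without WT replicate 3, 0.0128 without KO replicate 1, 0.027 with DESeq2 and 0.00555 with no filter. Of 18 hepatocyte genes, 7 were lower by both adjustments, with G6pc at -2.08, Cebpa at -1.37, Rbp4 at -1.02 and Hpd at -0.90. The Hpd call was lost with library totals only (adjusted p = 0.132) and without the 10 most abundant genes in the totals (0.0946). Their median was -0.74 (camera adjusted p = 0.00168, and adjusted p = 0.297 with an estimated correlation).

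Among 18 endothelial genes, Tek (1.42) was higher and Kdr (30.6 to 15.3 CPM) and Flt1 (-0.74) were lower, or 1 gene, higher, adjusted over the list alone, at a median of -0.55 (camera adjusted p = 0.0574). Without WT replicate 1, WT replicate 3, KO replicate 2 or KO replicate 3, camera gave adjusted p = 0.0108, 0.0175, 0.0198 and 0.0463 for this list. On all 8 libraries, camera also called endothelial genes with DESeq2 (0.0253), limma-voom (0.0165), quality weights (0.00173), no filter (0.00416), upper-quartile factors (0.0481), library totals only (0.032) and totals without the 10 most abundant genes (0.0351). With quality weights, 12 members were called. The Kdr call was lost without WT replicate 2 or 4 or KO replicate 1, 3 or 4 (adjusted p = 0.0926, 0.0991, 0.0987, 0.0985 and 0.0758). Flt1 lost its call without the same 5 libraries (0.115, 0.129, 0.122, 0.118 and 0.0812). Kdr and Flt1 also lost their calls with upper-quartile factors (0.0613 and 0.0934), library totals only (0.229 and 0.437), totals without the 10 most abundant genes (0.182 and 0.344), the number series as a covariate (0.0985 and 0.0955) and the clock covariate (0.108 and 0.0963), and Flt1 with no filter (0.0551) and the stricter filter (0.0512). Egfl7 (-0.54, adjusted p = 0.0805) was not called in the main test, but was without WT replicate 3 (0.0239), with quality weights (0.00897), with the number series as a covariate (0.0494), with the clock covariate (0.0259) and with the GC and length offset without WT replicate 3 (0.0482).

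Check lists for other tissues showed few changes. In libraries that all read as male, 3 of 5 female-biased liver genes were called higher and 4 of 10 male-biased ones lower. Cyp2b13 and Cyp3a41a were higher in KO, while Hsd3b5 and Elovl3 fell. Xist had 0 to 10 counts per library and Y-linked genes were read in all 8. Of 5 female-biased genes tested, 3 were higher by both adjustments, Cyp3a41a and Cyp2b13 among them, at a median of 3.92 (camera adjusted p = 0.00252, adjusted p = 0.0832 with an estimated correlation, and 0.0854 with quality weights). Cyp2b9 of that list was not called (1.36, adjusted p = 0.324), but without WT replicate 2 it was at 4.73 with adjusted p = 7.8e-05, and limma-voom called it (adjusted p = 0.0142). Of 10 male-biased genes, 4 were lower by both adjustments, Slco1a1, Elovl3, Hsd3b5 (-2.36, and -1.69 without WT replicate 3) and Mup1 (-1.54, and -0.89 without WT replicate 3). The Mup1 call was lost without KO replicate 1 or 2 (adjusted p = 0.0541 and 0.0633) and with the clock covariate (0.0579). The median of that list was -0.61 with camera adjusted p = 0.0658, and camera gave 0.0322, 0.0214, 0.0196 and 0.0294 without WT replicate 1, 2, 3 or 4 and 0.0458 without KO replicate 4. On all 8 libraries camera called male-biased genes with DESeq2 (0.00537), no filter (9.4e-04), upper-quartile factors (0.0372), library totals only (0.00541) and the GC and length offset (0.0196).

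Of 14 clock genes, Hlf (-1.34) and Tef (-1.51) were lower by both adjustments, at a median of -1.22 (camera adjusted p = 0.0735). Camera gave 0.0194 without WT replicate 1 and 0.0458 without KO replicate 4 for clock genes. On all 8 libraries it called them with DESeq2 (0.0135), no filter (0.00272), upper-quartile factors (0.0372), library totals only (0.00541) and totals without the 10 most abundant genes (0.00794). The Tef call was lost without WT replicate 4 or KO replicate 1, 2 or 3 (adjusted p = 0.0656, 0.058, 0.0665 and 0.0626), with library totals only (0.0542), the number series as a covariate (0.0514) and the clock covariate (0.0686). Tef is itself part of the clock covariate, so the loss there says nothing about how firm the Tef call is. Per1 (-1.47, adjusted p = 0.0615) was called without WT replicate 1 (0.021) or 3 (0.0066), and Per3 (-1.31, adjusted p = 0.0666) without the same libraries (0.0111 and 0.0356), and both were called by DESeq2 (0.0284 and 0.0345) and with no filter (0.00159 and 0.00386), and Per1 with quality weights (0.00774). Of 3 adipocyte genes, Plin4 (-2.00) and Cfd (-1.66) were lower by both adjustments, at a median of -1.66 and a camera adjusted p of 0.293. The Cfd call was lost without WT replicate 1, 2 or 4 or KO replicate 1, 2 or 4 (adjusted p = 0.0565, 0.103, 0.0706, 0.089, 0.106 and 0.0934), with upper-quartile factors (0.0525), library totals only (0.112), totals without the 10 most abundant genes (0.097) and the clock covariate (0.0678), and without KO replicate 3 Cfd was at -2.59. Cidec (0.64, adjusted p = 0.228) was not called.

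Of 13 mitochondrially encoded genes, mt-Nd2 (-0.82) was lower by both adjustments, and the median was -0.34 (camera adjusted p = 0.198), or 0.09 with library totals only. The mt-Nd2 call was lost with library totals only (0.132) and without the 10 most abundant genes (0.0825). Camera called the list with DESeq2 (0.0378), with no filter (0.0325) and with the GC and length offset without WT replicate 3 (0.0028). In the main test mt-Nd3 (-0.83), mt-Co3 (-0.69) and mt-Nd1 (-0.34) were not called, while mt-Nd3 (0.0247) and mt-Co3 (0.0139) were with the GC and length offset, and all 3 were with that offset without WT replicate 3 (0.00699, 0.00638 and 0.00119 for mt-Nd3, mt-Co3 and mt-Nd1). With edgeR, 0 of 5 erythroid genes were called at a median of 0.69 (camera adjusted p = 0.482), 1 had an unadjusted p under 0.05, DESeq2 also called 0 and quality weights called 2. Hbb-bs was called without WT replicate 3 (adjusted p = 0.0481), with quality weights (0.00838), no filter (0.00688) and library totals only (0.0163), and Hbb-bs, Hbb-bt (0.72) and Hba-a2 (0.69) were called with the clock covariate (9.96e-04, 0.00465 and 0.0267). Alas2 (0.34) was called with library totals only (0.0169). Of 2 pancreatic acinar genes, edgeR called 0, DESeq2 1 and quality weights 1, with 1 at an unadjusted p under 0.05 and a median of 0.52 (camera adjusted p = 0.763). Cela2a of that list was called without WT replicate 3 (adjusted p = 0.00774), with quality weights (0.00196), upper-quartile factors (0.0462), library totals only (0.0105) and totals without the 10 most abundant genes (0.0143), and Cela1 (-0.20) was not. Of 4 sex chromosome genes, both tools called 0, and 0 had an unadjusted p under 0.05. Their median was -0.27 (camera adjusted p = 0.482), or 0.20 with library totals only, and Ddx3y (-0.67), Eif2s3y (-0.32), Uty (-0.22) and Kdm5d (-0.19) were not called, while Ddx3y was with the GC and length offset (adjusted p = 0.0196).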

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

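The tests of depth, of a KO library under a WT label, of clock genes and of Nr0b2 were chosen only after the results they address were seen. Each value given here is 1 library that lies far from the other 3 of its genotype on the log2 scale, by Dixon's criterion at 95%. Of 320 groups of 4 tested, 34 stood apart in this way. For independent groups of normal values, chance gives about 1 in 20. These groups share libraries and many of the genes were named for their results, so that rate is no measure of an excess here. Of the 34 values, 16 belong to WT replicate 3, which also stands apart on the second principal component at -92.9, against 18.0 to 40.7 in the other WT libraries.

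In WT replicate 3, the genes with higher CPM than the other WT libraries were Serpina7 (853 against 217 to 253), Mup3 (66780 against 13850 to 16510), Sult2a8 (4096 against 980 to 1102), Cebpa (428 against 218 to 233), mt-Co3 (222 against 53.1 to 59.6), S100a9 (3.68 against 0.704 to 0.860), Cbr3 (0.566 against 0.429 to 0.440), Ddx3y (188 against 70.7 to 76.6), Eif2s3y (208 against 73.6 to 74.9) and Uty (57.6 against 17.5 to 19.6). Spink1 read 0.142 CPM there, from 1 count, and 0 in the others. The Cbr3 value also rests on few counts, since 3 counts in WT replicate 3 correspond to 0.425 CPM. Lower than in the other WT libraries were Atp7b (9.63 against 27.4 to 32.0), Plin4 (2.97 against 11.1 to 13.6), Slco2b1 (81.0 against 175 to 194) and G6pc (112 against 513 to 624).

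Other WT libraries stood apart in single genes. Vcam1 was at 5.10 CPM in WT replicate 1 against 9.03 to 9.78, and Apoa2 was at 7170 there against 5616 to 5766. Cyp3a41a at 0.0880 CPM in WT replicate 1 and Cyp2b13 at 0.0615 in WT replicate 2 each rest on 1 count, with 0 in the others. Cyp7a1 was at 22.6 CPM in WT replicate 4 against 63.1 to 75.3.

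Among KO libraries, replicate 3 was low in Cyp7a1 (19.4 CPM against 104 to 136), Slco2b1 (59.3 against 82.8 to 85.0), Stard4 (30.3 against 60.8 to 66.2), Scd1 (2006 against 4390 to 4866) and Elovl3 (35.1 against 95.7 to 103), and high in Nr0b2 (48.8 against 9.10 to 11.2). Replicate 4 was low in the bile duct genes Spp1 (386 against 864 to 931), Epcam (10.4 against 25.5 to 29.7) and Tspan8 (23.5 against 74.1 to 84.4) and in Cx3cr1 (2.40 against 4.32 to 4.62), and high in Ctcflos (2.25 against 0.444 to 0.508). Replicate 1 was low in Icam1 (16.4 against 20.9 to 21.2) and Csf3r (1.40 against 3.12 to 3.56).

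Low Atp7b in WT replicate 3 was weighed against 3 technical explanations. Depth is excluded, since the upper exact Poisson bound was 12.2 CPM, under the 27.4 CPM of the lowest other WT library. A KO library under a WT label is excluded, since of 202 genes near 0 in the other 3 WT libraries and read in KO, WT replicate 3 reached the lowest KO library in 1 (0.495%). A first version of that test found it nearer the KO mean in 30.6% of 3711 genes called at least 2-fold without it, which decided nothing, and was replaced after that value was seen. GC content and transcript length may account for part of the low value, since its deviation of -1.60 on the log2 scale lay at percentile 9.0 among 200 genes of like GC content, length and level, whose median was -0.81 and whose lowest 2.5% began at -2.13, while a biological difference of this sample stays open and untested.

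Over 12460 genes, the deviation of WT replicate 3 from the other WT libraries fell with GC content (Spearman rho -0.486) and with exon length (-0.187), where genes are not independent replicates. With an offset that removes both trends, added after the data were seen, the Atp7b log2 fold change was -1.56, and -1.76 when WT replicate 3 was left out as well. Without the offset these values were -1.65 and -1.92, so the offset left most of the gap that this library makes.

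Cyp7a1 varied within both genotypes, and 2 relations were tested over the 8 libraries after centring each genotype. With Nr0b2, Pearson's r was -0.963 (exact permutation within genotypes, two-sided p = 0.026, adjusted p = 0.052) and Spearman's rho was -0.548 (permutation p = 0.212, adjusted p = 0.361), but without WT replicate 4 and KO replicate 3 r was -0.377, so the relation rests on those 2 libraries. With an index of clock genes, r was -0.535 (exact permutation p = 0.167, adjusted p = 0.167) and rho -0.333 (permutation p = 0.361, adjusted p = 0.361), and r was -0.382 without WT replicates 1 and 4. The criterion was moved from the raw to the adjusted p after the values were seen, and the raw p for Nr0b2 would have met it. A number series holds at most 3 libraries, too few for a correlation within it, so Nr0b2 level and time of day as sources of the spread cannot be told apart here, nor from other differences between samples.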

How the results depend on the processing

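The offset for GC content and exon length, alone and without WT replicate 3, and the clock covariate were chosen only after the data were seen. All other alternatives were fixed beforehand. For the number of called genes, the genotypes gave 4746. As many came from 1 of the 35 splits of the libraries into 4 and 4, the genotypes themselves. The highest of the other splits gave 0 with edgeR (3536 at an unadjusted p under 0.05). A share of 1 in 35 is the lowest this test can give. Every other split mixes WT and KO libraries, so the genotype difference adds to the spread within its groups and lowers its count. The test therefore ranks the genotypes first but does not exclude chance. Nor can it separate genotype from other differences between the WT and KO libraries.

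Atp7b stayed lower and called under every alternative that tests it, from -1.93 with quality weights to -1.28 with library totals only. Leaving out each library in turn gave -1.92 to -1.52. Calls of named genes kept their direction in every alternative run. Over those alternatives, 3581 values of named genes kept their side of the threshold, 65 passed it newly and 84 no longer passed it. List tests did so in 742, 40 and 34 cases, and 17 of the 34 came from the estimated correlation. Among the values that kept their side, 25 that were called in neither setting changed sign.

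Counts of called genes moved by over 1.5 times in several settings. With limma-voom and quality weights, 4280 genes were higher and 3946 lower. With library totals only, 4804 were higher and 642 lower (3379 and 395 at least 2-fold), and 9 bile acid genes were higher and 18 lower. Among lists called by camera, the median of the respiratory chain list alone changed sign there, to 0.0541, and 6 uncalled lists changed sign too (canalicular export, copper, endoplasmic reticulum stress, acute phase, sex chromosome and mitochondrially encoded). With totals that leave out the 10 most abundant genes, 4485 were higher and 743 lower (441 lower at least 2-fold), and 8 bile acid genes were higher. These settings move the median of all genes up, and the share of calls that were higher went from 58.5% to 69.0% with upper-quartile factors, 88.2% with library totals only and 85.8% without the 10 genes. Library totals kept 72.0% of the called genes.

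Without a filter, which tests more genes, 4244 were higher (3741 at least 2-fold). At an adjusted p under 0.01, 912 were lower, as the stricter threshold requires fewer. Leaving out 1 library gave 2325 to 4267 higher and 1315 to 3837 lower, and the upper ends of both came without WT replicate 3, the library that stands apart. The GC and length offset without that library called 4354 lower. With quality weights, the 4280 higher and 3946 lower genes were close to the counts without WT replicate 3, but the cause was not tested. DESeq2 called 6337 genes, 4706 of them among the 4746, and gave no adjusted p for some named genes, Mup3 among them. With the number series as a covariate, 4870 genes were called.

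No paired analysis was possible because replicate numbers follow accession order and pair nothing. The sex covariate was not run, since all libraries read as male. In the simulated data, 25.4% of 2-fold changes were recovered with 15539 genes tested and 89 called. The real data gave 4746 calls, so the adjusted threshold falls at a different unadjusted p there. The simulated recovery therefore does not carry over, and the share of 2-fold changes missed in the real data was not measured.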

Other observations

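The test of genes near the Atp7b locus, the marker lists named in these paragraphs and the names of Krt20 and of list members were chosen only after the genes with the largest changes were seen.

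In KO, 172 genes rose from at most 3 counts over the 4 WT libraries to 1 CPM or more. They lie on 21 chromosomes, 120 are protein-coding and 119 reached 1 CPM in all 4 KO libraries. At the KO level, the lowest expected WT count of any of them was 58.2, so WT depth is not the limit. Linkage to the targeted locus is excluded as the whole source, since 2 of them (1.16%) lie within 10 Mb of Atp7b, against 0.746% of all genes tested, or 118 genes, of which 45 were called. Intestinal tissue in the samples is excluded, since a list of abundant intestinal transcripts had a median of 0.136 CPM in KO, against 18.8 CPM for Muc13, Mep1a and Krt20. A release of most listed germline genes that DNA methylation silences to 1 CPM is excluded, since 1 of 20 (5%) made such a step, or 2 of 21 with Tex19.1, which prompted the test. Members with over 3 WT counts, such as Rhox5 and Sycp1, could not make that step. Without that limit, 5 of the 20 had a mean of 1 CPM or more in KO, against 2 in WT. Smaller rises and single germline loci of that kind, a strain difference away from the Atp7b locus and a change in the liver cells themselves stay open and were not tested.

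Of the 14 intestinal genes, 4 had enough counts to be tested. Vil1 (3.27) and Fcgbp (2.30) were higher and Lgals4 (-1.21) was lower in KO, and camera gave adjusted p = 0.544 over the 4 added lists. WT liver itself read 2 of the 14 at 1 CPM or more, Fabp2 at 234 CPM and Lgals4 at 15.9 CPM. Of the germline genes, 5 were tested, with Rhox5 (5.80) and Asz1 (5.22) higher, Sycp3 (-1.80) lower and camera adjusted p = 0.234. Rhox5, which went from 4 to 335 counts, and Tex19.2, from 0 to 67 counts (0.907 CPM), missed the limits narrowly. The median of that list was 0.0107 CPM in WT and 0.147 CPM in KO.

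A list of 21 genes of fetal liver and liver tumours was drawn up after Afp, Gpc3 and H19 had been seen among the changed genes, so its test is not independent of them. Of 16 tested, 11 were higher at a median log2 fold change of 2.91 (camera adjusted p = 8.6e-10, and adjusted p = 0.0578 with an estimated correlation). Afp rose from 3.14 to 52.8 CPM, Gpc3 from 1.94 to 44.7 CPM and Golm1 from 5.25 to 57.6 CPM. Igf2 and Dlk1 had too few counts to be tested.

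In a list of 19 methionine cycle and DNA methylation genes, Mat1a (-0.78), Ahcy (-1.20), Gnmt (-1.24), Gamt (-1.26), Pemt (-0.68) and Tet3 (-0.74) were lower and Uhrf1 (3.49) was higher. The median was -0.56, and camera gave adjusted p = 0.234.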
